A study of Mus musculus with 2 samples.

How the data were processed

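Visium spatial gene expression, which captures polyadenylated RNA on a slide of barcoded spots, had been measured on coronal sections of the forebrain of ICR mice, an outbred strain, with 1 section at embryonic day 17 (E17) and 1 at postnatal day 0 (P0). The deposited matrices hold raw counts of unique molecular identifiers (UMIs) per gene and spot, with no normalization, for the spots that remained after the filter of the authors' pipeline. Space Ranger 1.2.0, Seurat 3.2.3 and the mm10 build are listed per the submitters' processing notes. Their roles and the version of the gene annotation are not given in the sources used here. Positions of spots and images were not used here, so a region below is a cluster of spots named by its genes and not an outlined area. All deposited spots were kept in the main results. The gene tables hold 32285 genes, of which 40 share a symbol with another gene and were kept apart by identifier. Coordinates were taken from GENCODE M21 on the GRCm38 build, which holds 32235 of the identifiers.

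A spot covers several cells, and spots of 1 section are not replicates. With 1 section per stage no test was run and no p-value was computed. Counts were summed over all spots of a section, or of a cluster, and scaled by the total UMI count of that section or cluster to CPM. Levels carry exact Poisson intervals and folds carry exact Clopper-Pearson intervals, both at 95% and both covering counting error only, not differences between animals or sections. A gene was called higher in a section when it had at least 20 CPM there, at least 100 UMIs over both sections and a ratio of at least 2. A gene with 0 UMIs in a section was set to a floor of 3 counts over that section and its fold was written as a lower bound.

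The 43 gene lists, 23 of markers of regions and cell types and 20 of processes, were fixed before the data were examined, as were the size rule, the rule for naming genes, the clustering parameters and most alternatives. A list was summarised by the median log2 fold, P0 over E17, of its members with at least 5 CPM in either section. Intervals of medians came from 500 redraws of the counts. The percentile of each median among 10000 random lists of equal size, matched on mean level in 20 bins, is a description of these libraries and not a test. The rule for naming genes took the 12 genes of largest fold in each direction, without mitochondrial, ribosomal protein, hemoglobin and sex-linked genes and predicted gene models. It also took up to 4 members of each list, up to 5 leading genes of each cluster, Nr4a2 with all claustrum and subplate list members, the 10 genes of highest correlation with Nr4a2, and 8 genes per direction in each compared class. In the compared classes the 30 leading genes of either cluster were also left out, because they had defined the clusters.

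Spots of each section were clustered on their own from log-normalized counts, 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 1. Mitochondrial, ribosomal protein, hemoglobin and sex-linked genes were kept out of the variable genes. Nr4a2 and the claustrum and subplate lists were kept out as well, a choice made after a first clustering with them had been seen. Leading genes were ranked by the ratio of CPM inside and outside a cluster, with 10 CPM added to both, among genes found in at least 25% of its spots. A cluster took the name of a marker list when at least 3 of its markers were among the 30 leading genes and no other list had more markers among the first 10. This naming rule was set after clusters and some fold values had been seen. Clusters of the sections were also matched by number as reciprocal best matches with at least 6 shared leading genes, likewise after the data had been seen. No doublet caller was run, because a spot holds several cells by design, and sizes of clusters were not compared between the sections.

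Across spots, Spearman correlations of Nr4a2 CPM with every gene found in at least 10% of the spots were computed, and genes at 0.3 or more were counted. The reliability of Nr4a2 was estimated by splitting its UMIs of each spot into 2 random parts 20 times. Mean z-scores of the claustrum and subplate lists were correlated over the 10% of spots highest in Nr4a2. In simulated data made from these libraries, the size rule recovered 50 of 50 genes at 2.5-fold, 50 at 4-fold and 50 at 8-fold, and 0 of 50 at 1.5-fold. It called 0 of 8064 unchanged genes. The simulated counts held Poisson counting error only, with no difference between animals or planes of section. They therefore give no rate of false calls for the real sections.

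Alternatives replaced the total by TMM factors (1.03 for E17 and 0.975 for P0) or by the median of ratios, weighted spots alike, thinned spots to 5000 UMIs, required 2000 UMIs per spot, changed each threshold, gave both sections the same mix of joint clusters with at least 10 spots per section, and varied the clustering and the correlation. Counts were handled in Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and leidenalg 0.10.2. TMM factors came from edgeR 4.0.16 in R 4.3.3, and plots were drawn with matplotlib 3.10.9.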

Results

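Gene expression was measured in spots of 1 coronal forebrain section from an E17 mouse and 1 from a newborn (P0) mouse, and the title of the series names change over time and heterogeneity of the claustrum as its subjects. The E17 section held 979 spots and 27186009 UMIs, with a median of 28623 UMIs per spot and a range from 357 to 53087. The P0 section held 1243 spots and 31245223 UMIs, with a median of 25614 per spot and a range from 150 to 57717. A median of 7560 genes per spot was found at E17 and 6962 at P0, and of 2896.5 and 2791 after each spot had been thinned to 5000 UMIs, which left out 5 and 4 shallower spots. Mitochondrial transcripts were 1.46% of the UMIs at E17 and 2.22% at P0, and hemoglobin transcripts were 0.119% and 0.0248%. Each stage has no replicate, so intervals below cover counting error only.

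The first comparison asked which genes differed between the stages over the whole section. Genes of the hypothalamus led those higher at P0, and genes of the striatum were among the 12 of largest fold. Oxt, which encodes oxytocin, stood at 139 CPM at P0 (4346 UMIs) against 0.0736 CPM at E17 (2 UMIs), a ratio of 1891 with an interval from 523 to 15617. Avp, which encodes vasopressin, stood at 669 CPM against 0.956 CPM, 699-fold higher at P0 (477 to 1071). Of their UMIs at P0, 70.7% for Oxt and 78.4% for Avp lay in a single cluster of spots, named below for the hypothalamus. Crabp1, a retinoic acid-binding protein, was 8.48-fold higher at P0 (7.53 to 9.58), with 11.04 CPM at E17 and 93.6 CPM at P0. Penk, the enkephalin precursor of striatal neurons, was among the 12 of largest fold, 2.92-fold higher (2.59 to 3.29). The immediate early gene Egr1 was 3.81-fold higher (3.21 to 4.55), and Agt, the angiotensinogen gene of astrocytes, 4.97-fold (4.14 to 6.01). Others were the amylase gene Amy1 (8.57-fold), Sft2d1 (7.32-fold), the tubulin gene Tuba4a (3.14-fold), the copine gene Cpne6 (3.05-fold) and Mid1 (3.01-fold), which spans the pseudoautosomal boundary of the mouse X chromosome.

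The 12 genes of largest fold at E17 included genes of progenitors, of fetal growth and of other hypothalamic and pituitary cells. Gh, the growth hormone gene of the pituitary, had 1051 UMIs at E17 and 0 at P0, at least 403-fold higher at E17, and 64.4% of them lay in the meninges cluster. Pmch, the melanin-concentrating hormone precursor of lateral hypothalamic neurons, stood at 262 CPM at E17 against 12.5 CPM at P0, 20.98-fold higher at E17 (18.9 to 23.3), with 69.7% of its E17 UMIs in the hypothalamus cluster. Eomes, a transcription factor of intermediate progenitors, was 4.93-fold higher at E17 (4.10 to 5.97), and Neurog2, which drives pallial neurogenesis, 3.39-fold (2.91 to 3.95). The imprinted genes Mest and H19 were 3.63-fold (3.38 to 3.90) and 3.57-fold (3.36 to 3.80) higher at E17. Nkx2-1, a patterning factor of the ventral forebrain, was 3.66-fold higher (3.22 to 4.18), and 55.0% of its E17 UMIs came from the hypothalamus cluster. The choroid plexus genes Ttr, which encodes transthyretin, and Ecrg4 were 3.73-fold and 4.39-fold higher. Within the choroid plexus clusters themselves, Ttr was higher at P0, at 74930 CPM against 60116 CPM at E17. The others were the tight junction genes Patj (4.63-fold) and Cldn11 (3.94-fold) and the zinc finger gene Zfp949 (4.47-fold).

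By the size rule, 36 genes were higher at P0 and 74 at E17 among the 8576 genes that met its level and count minimums, and 7950 (92.7%) differed by less than 1.5-fold. Under the median of ratios the split was 44 and 49 genes, so the size of the surplus at E17 depended on the scaling. It was 32 and 41 genes with the same mix of joint clusters in both sections, some of which were led by different genes at E17 and P0. With that mix the log2 folds moved from 3.08 to 2.13 for Crabp1, from -2.30 to -1.44 for Eomes, from -1.90 to -1.05 for Ttr, from -2.13 to -1.40 for Ecrg4, from -1.84 to -1.13 for H19 and from -1.98 to -1.36 for Cldn11. After thinning those of Agt and Avp moved from 2.31 to 2.90 and from 9.45 to 10.33. On the GRCm38 build, Oxt (ENSMUSG00000027301) spans 130576173 to 130577054 and Avp (ENSMUSG00000037727) 130580620 to 130582554 on chromosome 2, Pmch (ENSMUSG00000035383) 88091072 to 88092375 on chromosome 10, Eomes (ENSMUSG00000032446) 118478212 to 118486132 on chromosome 9, and Nr4a2 (ENSMUSG00000026826) 57106830 to 57124003 on chromosome 2. The rostrocaudal level of each coronal section is not given in the sources used here. Genes of structures present in 1 section only therefore cannot be separated from genes that differ with stage.

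**Figure D1:**
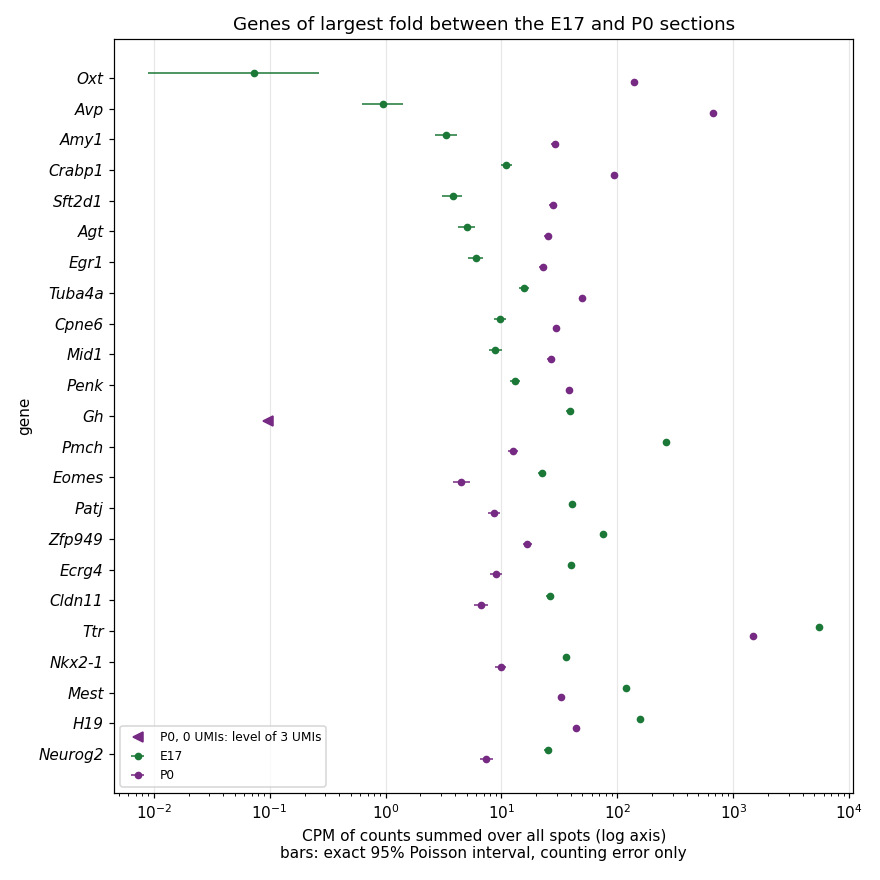
Levels of 23 of the named genes of largest fold on a log axis, in CPM of counts summed over all spots, with E17 in green, P0 in purple and bars for exact 95% Poisson intervals that cover counting error only. Oxt and Avp were the farthest apart among genes higher at P0, at 0.0736 and 139 CPM and at 0.956 and 669 CPM, and the triangle marks Gh at P0, with 0 UMIs, at the level of 3 UMIs.

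Gene lists of dividing and immature cells were lower at P0. All 15 genes of the cell cycle list were higher at E17, 5 of them past the size rule, with a median log2 fold of -1.0004. The mitotic genes Ccnb1, Mki67 and Cenpf were 2.54-fold, 2.44-fold and 2.35-fold higher at E17. The subpallial progenitor list had a median of -0.81 over 9 genes, all higher at E17, led by Nkx2-1 and Mki67. It shares Mki67 and Top2a with the cell cycle list. The pallial progenitor list had a median of -0.39 over 10 genes, 9 of them higher at E17, led by Eomes and Neurog2. The fetal growth and imprinted list had a median of -0.83 over 13 genes, 12 of them higher at E17, with Igf2bp1, an RNA-binding protein of fetal tissue, 2.80-fold and the Notch ligand family gene Dlk1 2.35-fold higher. Sox11, a factor of newborn neurons, was 2.17-fold higher at E17, while Gap43, a protein of growing axons, was 1.40-fold higher at P0, and the neurite growth list as a whole had a median of 0.07.

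Blood, choroid plexus and meningeal lists were also lower at P0. Blood genes had a median of -2.50 over 4 hemoglobin genes, from Hba-a2 (8.13-fold higher at E17) to Hba-a1 (3.13-fold). The choroid plexus list had a median of -1.75 over 4 genes, with the folate receptor gene Folr1 4.32-fold higher at E17. The meninges list had a median of -0.95 over 8 genes, with the matrix gene Ogn 2.91-fold and the prostaglandin D synthase gene Ptgds 2.17-fold higher at E17. With the same mix of joint clusters in both sections the medians of the choroid plexus and meninges lists were -1.08 and -0.14. Vessel genes had a median of -0.26, with the glucose transporter gene Slc2a1 1.43-fold higher at E17.

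Lists of hypothalamus, striatum, thalamus and interneurons were higher at P0. The hypothalamus list had a median of 1.01 over 8 genes, with the transcription factor gene Six6 7.68-fold higher at P0 and Pomc, the precursor of melanocortins, 2.12-fold higher at E17. That median was 5.24 with a minimum of 10 CPM. All 15 measured striatum genes were higher at P0 (median 0.46), including the adenosine receptor gene Adora2a (2.52-fold) and the substance P precursor Tac1 (2.498-fold). The 7 measured genes of dopamine and opioid signalling were higher too (median 0.83), but this list shares genes such as Penk and Tac1 with the striatum list. All 7 thalamus genes were higher at P0 (median 0.53), led by Gbx2 (1.75-fold), a factor of thalamic neurons, and Calb2 (1.57-fold), a calcium-binding protein. Interneuron genes had a median of 0.30, with somatostatin (Sst) 1.56-fold higher at P0 and Maf, a factor of interneurons from the medial ganglionic eminence, 1.67-fold higher at E17. With the same mix of joint clusters in both sections the medians of the hypothalamus, thalamus and interneuron lists were 0.65, 0.23 and 0.37. The claustrum and subplate lists had medians of 0.42 over 6 genes and 0.40 over 5 genes.

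Synaptic vesicle and mitochondrial lists were higher at P0, and receptor lists held members of both directions. Of 14 synaptic vesicle genes 13 were higher at P0 (median 0.32), including Sv2b (1.66-fold) and Syp, which encodes synaptophysin (1.56-fold). Grin1, the obligatory subunit of NMDA receptors, was 1.63-fold higher at P0, and the glutamate receptor list had a median of 0.19, with 8 genes higher at P0 and 4 at E17. The GABA list also had a median of 0.19, with the receptor subunit gene Gabra5 1.58-fold and the chloride exporter gene Slc12a5 1.43-fold higher at P0. Nrgn, a calmodulin-binding protein of dendritic spines, stood at 166 CPM at E17 and 371 CPM at P0, 2.24-fold higher, in a postsynaptic list whose median was 0.11. All 12 measured genes of the mitochondrial genome were higher at P0 (median 0.61), from mt-Nd1 at 1.66-fold downward. All 14 nuclear genes of oxidative phosphorylation were higher too (median 0.27), with Uqcrb of complex III at 1.32-fold.

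Lists of astrocytes and oligodendrocytes were higher at P0. Oligodendrocyte precursor genes had a median of 0.57 over 8 genes, all higher at P0, with Bcas1 1.85-fold and the proteoglycan gene Cspg4 1.61-fold. Myelin genes had a median of 0.51 over 5 genes, with Mag 1.88-fold and Mbp 1.42-fold higher at P0 and Cldn11 higher at E17. Astrocyte genes had a median of 0.40 over 11 genes, with the filament gene Gfap 2.96-fold and the water channel gene Aqp4 2.29-fold higher at P0. The matrix list of the brain had a median of 0.22, with the proteoglycan gene Cspg5 1.55-fold higher at P0, and microglial genes a median of 0.12, with 5 genes higher at P0 and 4 at E17. The glucocorticoid and thyroid hormone list had a median of 0.29, with the hormone-responsive factor Klf9 1.92-fold and the metallothionein gene Mt1 1.80-fold higher at P0. Heat shock genes had a median of 0.27, with Hspb1 1.58-fold higher.

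Cortical layer lists had medians inside the central 95% of random lists. The upper layer list had a median of -0.22, with Pou3f2, a factor of upper layer neurons, 1.97-fold higher at E17, and the deep layer list a median of -0.17, with Zfpm2 1.64-fold higher at E17. In the hippocampus list (median -0.14) the neurogenic factor Neurod1 and Zbtb20 were 2.48-fold and 2.43-fold higher at E17 and Wfs1 2.03-fold higher at P0. Fos was 4.62-fold higher at P0 and Btg2 2.17-fold higher at E17, and the immediate early list had a median of 0.28 that reversed to -0.06 after thinning and to -0.15 with a minimum of 10 CPM. Ketone and fatty acid genes had a median of 0.11, ribosomal proteins 0.09 and tissue outside the brain 0.34 over 2 genes. Medians near 0 were found for glycolysis (0.04, with the hypoxia-responsive gene Vegfa 1.63-fold higher at E17), interferon genes (0.02), the circadian clock (-0.01), the septum (-0.04, with Lhx8, a factor of cholinergic neurons, 14.3-fold higher at P0), ependyma (-0.06) and Cajal-Retzius cells (-0.08). The last 4 turned positive under the median of ratios, and the circadian, septum and ependyma medians under TMM as well. The medians of 26 of the 43 lists lay outside the central 95% of those of random lists of matched level.

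**Figure D2:**
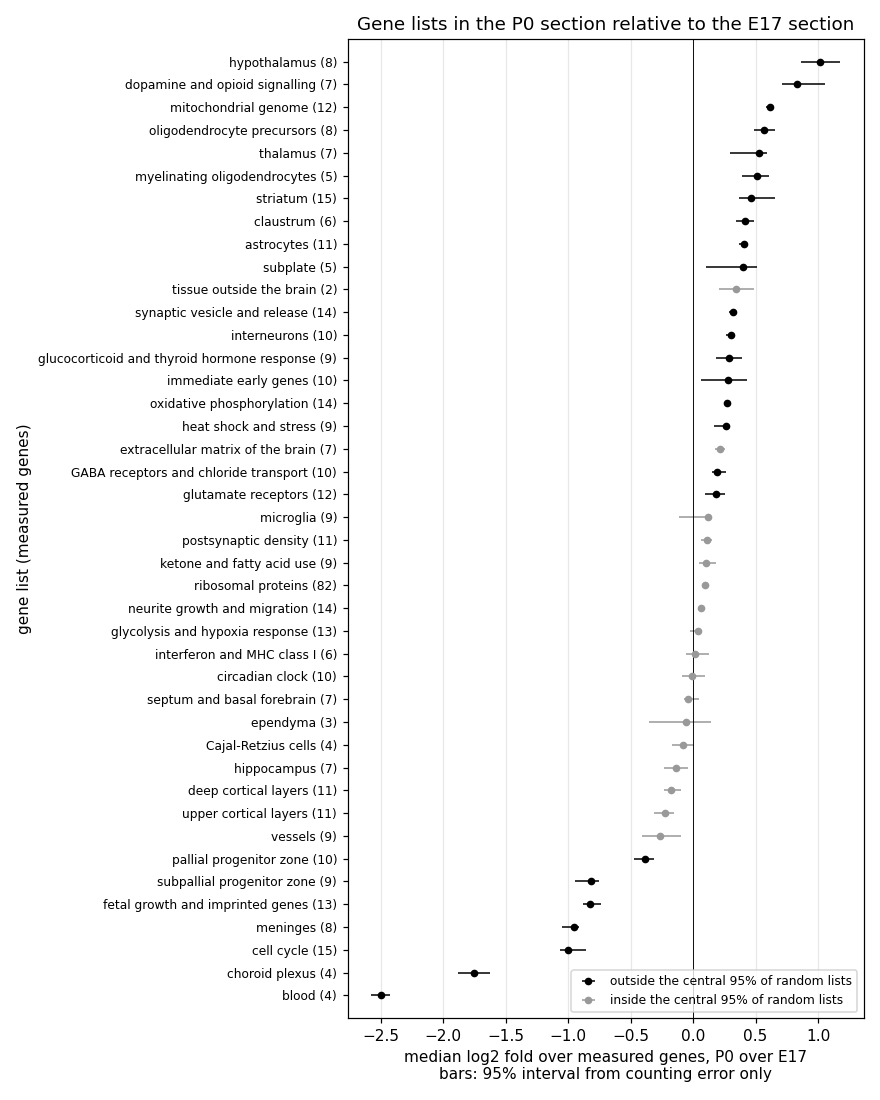
Median log2 fold, P0 over E17, of each gene list over its measured genes, with bars for 95% intervals from counting error only and black points for medians outside the central 95% of random lists of matched level. The lists run from hypothalamus at 1.01 down to blood at -2.50, with cell cycle at -1.0004, and sex-linked genes were left out, while the medians of the circadian, septum, ependyma and Cajal-Retzius lists, all drawn just under 0, turned positive under the median of ratios.

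The animals differed in sex-linked transcripts. Xist, the RNA that coats the inactive X chromosome, had 5936 UMIs at E17 and 1 at P0. The Y-linked genes Eif2s3y and Ddx3y had 0 UMIs at E17 and 2139 and 1189 at P0. Kdm5d had 1 and 634, and Uty 0 and 380, which put the median of the sex-linked list at 8.43 with zeros at the floor. X-linked genes as a whole had a median log2 fold of -0.04 over 289 genes, against -0.06 for 8267 autosomal genes.

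The second comparison asked how the stages differed within regions. Spots formed 14 clusters at E17, 9 of them named, and 17 clusters at P0, 10 of them named. Upper cortical layers were marked in both sections by Mef2c, the thalamus by Gbx2 and Tcf7l2, choroid plexus by Ttr and Folr1, and meninges by Ptgds and collagen genes. The hypothalamus cluster was led by Pmch and Nkx2-1 at E17 and by Avp and Oxt at P0, so the class was led by different genes in the sections. The E17 pallial progenitor zone was led by Eomes and Neurog2 and was matched to an unnamed P0 cluster led by Igfbpl1, Fam210b and Rlbp1, called the germinal pair below. A pair led by Gng8 and Pou4f1 at E17, the latter a factor of habenular neurons, was joined at P0 by Sspo, which encodes the secreted protein of the subcommissural organ. Another pair was led by Slc6a4, the serotonin transporter gene, and Rora. Of the 12 matched pairs, 0 included the P0 striatum clusters, which were led by Sst and Pbx3 and by Crabp1 and Tac1, or the E17 subpallial cluster led by Dlx2 and Dlx1. The unnamed E17 cluster led by Sst, Lmo3 and Rprm, with 111 spots, was not matched either.

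In cortical clusters, Nrgn was higher at P0 and the fetal growth and imprinted list was higher at E17. Neither was particular to cortex. Nrgn was also higher at P0 in choroid plexus (4.59-fold), the germinal pair (2.73-fold) and the interneuron class (2.25-fold), and the list was higher at E17 in all 12 matched pairs. In upper layers Nrgn stood at 160 CPM at E17 and 503 CPM at P0, 3.14-fold higher (2.80 to 3.53). The peptide gene Cck was 2.85-fold (2.41 to 3.37), the chemokine gene Cxcl14 4.54-fold (2.84 to 7.58) and the zinc finger gene Tshz2 4.998-fold (3.07 to 8.54) higher at P0. H19 and Dlk1 were 7.02-fold and 4.42-fold higher at E17 in these layers, but so was the meningeal collagen gene Col1a1 (3.21-fold), and the meninges list had a median of -1.27 there. Over the whole E17 section 43.7% of H19 UMIs lay in the meninges cluster. In the pair led by Fezf2 and Npy, named for deep layers at E17 and unnamed at P0, Nrgn was 4.64-fold (4.08 to 5.30), the dendritic gene Ddn 5.10-fold, the vesicle release gene Doc2a 3.96-fold and Synpr, a vesicle protein on the claustrum list, 3.70-fold higher at P0, and Mest was 3.07-fold higher at E17. By the size rule 24 genes were higher at P0 and 64 at E17 in upper layers, and 53 and 78 in the Fezf2 and Npy pair. The upper layer counts depended on the clustering, with 32 and 244 genes from 15 principal components and 37 and 76 from joint clustering.

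In the germinal pair, genes of glia were higher at P0. Cst3, a cystatin of astrocytes, went from 604 CPM at E17 to 1725 CPM at P0 (2.85-fold, 2.61 to 3.12), and the astrocyte genes Mlc1 and Hepacam were 2.76-fold and 2.61-fold higher. Olig1, a factor of the oligodendrocyte lineage, was 2.54-fold higher (2.05 to 3.15). The astrocyte and oligodendrocyte precursor lists had medians of 1.06 and 1.08 in this pair, and the cell cycle list -0.64. Prdm8 was 3.31-fold higher at E17. The pair had 39 genes higher at P0 and 32 at E17.

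In the thalamus Thy1, a surface protein of maturing neurons, was 2.95-fold (2.52 to 3.46), Tuba4a 3.78-fold and Rwdd2a 4.05-fold higher at P0, while H19 was 4.36-fold and Lhx6 2.91-fold higher at E17, with 29 genes higher at P0 and 83 at E17 (49 and 89 at Leiden resolution 1.5). This class joined E17 cluster 5 with P0 clusters 3 and 10. P0 cluster 10 held Slc18a2, Lef1, Rora and Slc6a4 among its 30 leading genes. So did the unnamed E17 cluster of the Slc6a4 and Rora pair, which lay outside the class, so the class did not compare like with like. Between E17 cluster 5 and P0 cluster 3 alone, 42 genes were higher at P0 and 107 at E17. There Tuba4a was 3.93-fold higher at P0 and H19 5.31-fold higher at E17. In the hypothalamus the kinase gene Rps6ka2 was 10.1-fold (5.26 to 21.7), Six6 4.94-fold and Foxb1 3.35-fold higher at P0, and Mest (241 CPM against 26.4, 9.13-fold), Neurod1 (4.17-fold) and the cyclin gene Ccnd2 (3.67-fold) were higher at E17, with 51 and 128 genes. These counts were 115 and 144 at resolution 1.5, 117 and 142 with 15 principal components and 88 and 141 with joint clustering. In the interneuron class, whose clusters shared Slc32a1 and Gad2 among their 30 leading genes, Npy was 2.23-fold and Thy1 2.25-fold higher at P0, and Bhlhe22 (3.01-fold) and Ccnd2 (2.73-fold) were higher at E17, with 10 and 64 genes. Naming from 50 leading genes took another P0 cluster and gave 73 and 161, and under 4 other clusterings the class could not be compared. The P0 cluster of that class was led by Pmch and Pax6 and held as many striatum markers as interneuron markers among its first 10 genes. It took its name from Gad1, Gad2 and Slc32a1 alone, and the clusters of the class also shared Isl1, Pax6 and Nkx2-2. The folds of this class therefore cannot be assigned to interneurons.

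In meninges, a few genes of lipid use and of astrocytes were higher at P0, while the ketone and fatty acid list as a whole had a median of -0.06. Cpt1a, which brings fatty acids into mitochondria, was 2.87-fold (1.96 to 4.21) and Angptl4, an inhibitor of lipoprotein lipase, 2.91-fold (2.11 to 4.03) higher. Gfap and Aqp4 were 4.75-fold and 4.36-fold higher, as was the neuronal peptide gene Cck (2.78-fold), and Dlx1 3.33-fold higher at E17. In choroid plexus Dlk1 was 6.40-fold, the plasminogen activator gene Plat 4.36-fold and the matrix gene Tnc 3.38-fold higher at E17, whereas neuronal genes such as Nrgn (4.59-fold), Sst (3.54-fold) and Gad1 (2.45-fold) were higher at P0 in these spots. The size rule gave 30 and 52 genes in meninges and 24 and 81 in choroid plexus, where the surplus at E17 depended on the clustering: with 15 principal components 116 genes were higher at P0 and 84 at E17, with joint clustering 21 and 24, and at resolution 1.5 53 and 120.

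In the pair led by Nts, Crym and Lpl, Nrgn (3.48-fold) and the purine enzyme gene Gda (3.22-fold) were higher at P0 and Eomes (3.08-fold) at E17. In the pair led by Slc17a7, Lmo3 and Plxnd1, Crabp1 was 8.75-fold and Tac1 3.05-fold higher at P0, Lpl 4.74-fold higher at E17, and the subplate list had a median of 1.73. This pair held 36 spots at E17 and 83 at P0, and the E17 cluster led by Sst and Lmo3 stayed outside it. In the Gng8 and Pou4f1 pair, Gbx2 was 3.27-fold higher at P0 and Neurod1 3.67-fold and Sox11 2.61-fold higher at E17. In the Slc6a4 and Rora pair, Thy1 was 4.56-fold and Igfbp5 2.88-fold higher at P0 and Sp9 6.84-fold and Tcf4 2.61-fold at E17.

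The fetal growth and imprinted list was lower at P0 in all 12 pairs, with medians from -0.99 to -0.23, and the cell cycle list in 10 of the 12, with medians from -1.10 to 0.11. The meninges list, whose tissue is rich in H19, was lower at P0 in 11 of the 12 pairs as well, with medians from -1.92 to 0.55. Oligodendrocyte precursor, oxidative phosphorylation and synaptic vesicle lists were higher at P0 in all 12 pairs, with lowest medians of 0.11, 0.05 and 0.02. Lists of single regions behaved alike. The striatum list was higher at P0 in all 12 pairs (0.07 to 0.85) and the hypothalamus list in 11 of the 12 (-0.24 to 3.27). A direction shared by the pairs therefore does not separate stage from the mix of regions or from RNA carried over the section. The mitochondrial genome list was higher at P0 in 11 of the 12, from 1.72 in choroid plexus to -0.03 in upper layers, and the astrocyte list in 10 of the 12. The thalamus list, higher at P0 over the whole section, was higher at E17 in 9 of the 12 pairs, with medians from -0.78 to 0.76, and the interneuron and subplate lists were higher at E17 in 6 of the 12. Of 2859 genes that met the minimums in every pair, 1 was at least 1.5-fold higher at P0 in all 12 pairs, Gm47283, a gene model annotated on chromosome Y with 9400 UMIs at E17 and 20925 at P0, and 6 at E17. These were Xist, Hbb-bs, Hba-a2, AC149090.1, Rsrp1 (log2 fold from -1.04 to -0.60) and Mir124a-1hg (-2.02 to -0.99), the host transcript of a neuronal microRNA; they were chosen after their values were seen. Transcripts of restricted source were found in every cluster of a section outside their source, Pmch at E17 at 64.9 to 166 CPM and Avp at P0 at 73.1 to 1565 CPM, and Avp, Oxt, Pmch, Ttr and hemoglobin genes were therefore set aside in the accounts of single regions. Some named genes differed alike in several classes. Zfp949 was higher at E17 in hypothalamus (6.37-fold), thalamus (3.75-fold), meninges (4.47-fold), choroid plexus (5.04-fold) and the interneuron class (4.25-fold). Amy1 was higher at P0 in hypothalamus (7.87-fold) and thalamus (8.08-fold). Whether these genes differ between the animals apart from stage was not tested. Nr4a2, claustrum and subplate genes did not take part in forming the clusters.

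The third comparison concerned the claustrum through Nr4a2, a nuclear receptor gene known as a marker of the claustrum and subplate. Nr4a2 was at nearly equal levels in the sections, 43.3 CPM at E17 (1178 UMIs) and 44.1 CPM at P0 (1378 UMIs), a ratio of 1.02 (0.941 to 1.10). At E17 its highest level was in the Gng8 and Pou4f1 cluster, at 229 CPM (197 to 264), followed by upper cortical layers at 98.0 CPM (86.0 to 111), the Nts and Crym cluster at 62.9 CPM and deep layers at 46.4 CPM. At P0 the order differed, with 122 CPM (109 to 136) in the cluster led by Neurod6, Hs3st2 and Npy, 111 CPM in that led by Crym and Nts, 98.5 CPM (81.9 to 118) in that led by Sspo and Esm1, and 80.6 CPM in that led by Slc17a7 and Lmo3. The lowest level of a cluster was 15.3 CPM at E17, in thalamus, and 7.65 CPM at P0, in the smaller of the 2 thalamus clusters, the larger of which stood at 13.2 CPM. No cluster of either section was named for the claustrum or the subplate. Their genes had been kept out of the clustering and several had few UMIs, so this absence says little about these regions. With these genes kept for clustering, neither was a class named in both sections.

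**Figure D3:**
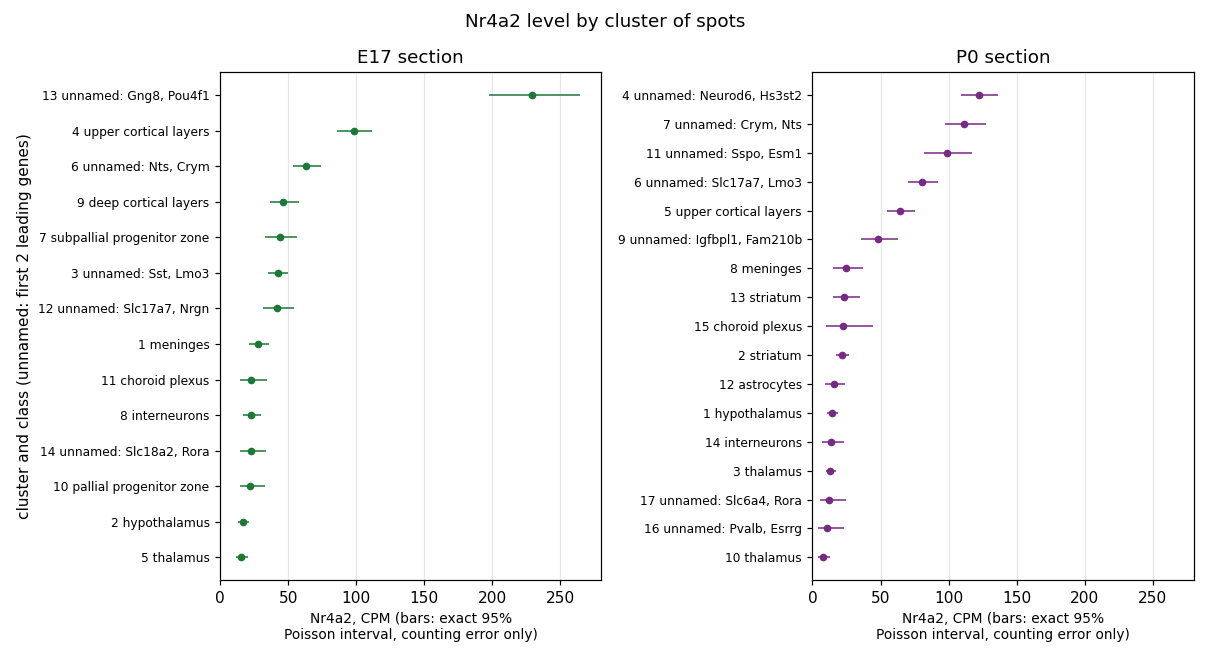
Level of Nr4a2 in each cluster of spots, in CPM, in the E17 section on the left and the P0 section on the right, with bars for exact 95% Poisson intervals that cover counting error only. At E17 the cluster led by Gng8 and Pou4f1 stood apart at 229 CPM, and at P0 the 4 highest clusters lay between 80.6 and 122 CPM.

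The other claustrum genes were spread over different regions. Gnb4, a G protein subunit gene, was 1.47-fold higher at P0 (1.40 to 1.55) and highest in thalamus, at 130 CPM at E17 and 160 CPM at P0. Oprk1, the kappa opioid receptor gene, was 2.19-fold higher at P0 (1.66 to 2.93), at 5.73 CPM. Lxn, a carboxypeptidase inhibitor, was 1.34-fold higher at P0 and highest in choroid plexus at E17 (148 CPM) and in the astrocyte cluster at P0 (182 CPM). Synpr was 1.33-fold higher at P0 and highest there in the striatum cluster led by Crabp1 (120 CPM). Nr2f2, a nuclear receptor gene of caudal forebrain, was 1.99-fold higher at E17 (1.92 to 2.06), and Gng2 1.10-fold higher at E17. Car3, a carbonic anhydrase gene, had 19 UMIs at E17 and 87 at P0 (3.98-fold, 2.40 to 6.93), of which 54 lay in the P0 cluster led by Sspo. Ntng2 had 10 and 16 UMIs and Npsr1 1 and 2, too few to compare, and Smim32 was not found in the gene tables.

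Among subplate genes Cplx3, a complexin gene, had 9 UMIs at E17 and 75 at P0, 7.25-fold higher at P0 (3.62 to 16.5). Its highest P0 levels were 13.6 CPM in the Sspo and Esm1 cluster (17 UMIs) and 12.2 CPM in the P0 cluster of the germinal pair (13 UMIs), against 3.56 CPM in the Slc17a7 and Lmo3 cluster and 3.39 CPM in the Neurod6 and Npy cluster. Ccn2 was at a ratio of 1.002 over the whole section, and its highest P0 level, 54.9 CPM, was in the Slc17a7 and Lmo3 cluster, against 41.7 CPM in meninges as its highest at E17. Nxph4 was 1.498-fold, Tmem163 1.38-fold and Inpp4b 1.32-fold higher at P0, and Moxd1 2.05-fold (1.53 to 2.76) and Lpar1 1.24-fold higher at E17. Within the Slc17a7 and Lmo3 pair, which also held much Nr4a2 at P0, the subplate list had its highest median. This pair set 36 E17 spots against 83 P0 spots. The unmatched E17 cluster led by Sst and Lmo3, with 111 spots, held Nr2f2 and Moxd1 among its 30 leading genes. In joint clustering, 132 E17 spots led by Sst, Nrgn and Lmo3 grouped with 79 P0 spots led by Slc17a7 and Lmo3. The pair may therefore not hold like tissue, and its subplate median cannot be assigned to stage.

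By Spearman correlation across spots, Nr4a2 went weakly with genes of cortical projection neurons. At E17 the highest Spearman correlations were with Neurod6, a factor of pallial neurons (0.22), and Id2 (0.21), and the rest of the first 10 included Add2, Mpped1, Thra, St6galnac5, Morn4, Mlip and Nin, down to 0.18. At P0 they were with Zbtb18 (0.29), Neurod6 (0.29) and Mpped1 (0.28), and the rest of the first 10 included Zeb2, Khdrbs3, Neurod2, Cd24a and Nrgn, down to 0.25. Of the claustrum and subplate genes Gng2 (0.14) and Ccn2 (0.12) had the highest correlations at P0, and Nr2f2 (-0.06 at E17 and -0.12 at P0) and Tmem163 (-0.08 and -0.09) were below 0 in both sections. With spots thinned to 5000 UMIs the highest correlation was 0.12 at E17, with Arid1b, and 0.20 at P0, with Mpped1. The count of genes at 0.3 or more was 0 of 12202 at E17 and 0 of 11774 at P0, where Pearson correlation gave 2. The highest Pearson correlation at E17 was 0.21, with Pou4f1, the factor of habenular neurons. With a mean of 1.203 and 1.11 Nr4a2 UMIs per spot, the reliability of its level was estimated at 0.48 and 0.57. This gives approximate ceilings of 0.69 and 0.75 for its correlations. Both random parts were divided by the same spot total, which may raise these estimates. Among the 98 and 124 spots highest in Nr4a2, the claustrum and subplate scores had correlations of 0.11 and 0.10, against 0.011 and -0.018 over all spots.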

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

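The alternatives that named clusters from 50 leading genes, kept the Nr4a2, claustrum and subplate genes for clustering, paired clusters by number or left out the cluster of highest Nr4a2 were chosen after the data had been seen. No paired analysis was possible because each stage has 1 section. Counts of genes followed the thresholds by construction: with minimums of 10 CPM, 50 CPM and none, 59, 10 and 146 genes were higher at P0 and 144, 28 and 365 at E17, and with folds of 1.5 and 3 the counts were 190 and 14 at P0 and 436 and 19 at E17. Scaling moved the median of all genes by under 0.1, from -0.06 to 0.01 under TMM and 0.03 under the median of ratios. The median of ratios left 49 genes higher at E17, all among the main 74, because it raised every P0 level alike, and the same mix of joint clusters left 41, of which 38 were among the main 74, against 32 higher at P0 (the cause was not tested). Under the alternatives other than thresholds, 32 to 48 genes were higher at P0 and 41 to 98 at E17, with the 98 from thinned spots (60 among the main 74) and 89 from spots weighted alike. All 24 named genes kept their direction under the 5 alternatives tried on them. Of the 43 list medians, 4 changed sign under each of the same mix, thinning, no minimum level and the median of ratios, 3 under TMM and with a minimum of 10 CPM, 2 with spots weighted alike and 1 with totals without mitochondrial, ribosomal protein and hemoglobin genes. They were those of the septum, ependyma, Cajal-Retzius, microglia, circadian, glycolysis, interferon and immediate early lists. Only the last had a main interval clear of 0 on reversing, to -0.057 with thinned spots and -0.15 with a minimum of 10 CPM (the cause was not tested).

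Genes correlated with Nr4a2 at a threshold of 0.2 numbered 2 at E17 and 41 at P0, and at the main threshold of 0.3 Pearson correlation gave 2 at P0, against 0 by Spearman. In thinned spots the highest correlation dropped from 0.22 to 0.12 at E17 and from 0.29 to 0.20 at P0, each with another gene. The score correlation was 0.011 at E17 and -0.018 at P0 over all spots. Within classes, resolution 1.5 gave 53, 115 and 49 genes higher at P0 in choroid plexus, hypothalamus and thalamus. Joint clustering gave 21 genes higher at P0 and 24 at E17 in choroid plexus, and 88 and 37 higher at P0 in hypothalamus and upper layers. With 15 principal components, 116 genes were higher at P0 and 84 at E17 in choroid plexus, which turned the surplus, with 117 at P0 in hypothalamus and 244 at E17 in upper layers. Naming from 50 leading genes gave 73 and 161 genes in interneurons, at P0 and E17, from another P0 cluster. The cause was not tested for the other class counts, but each of these settings moved spots between classes. Upper layers and interneurons had no value at resolution 0.6, and interneurons had none under joint clustering, 15 principal components or with the kept genes. Depth limits the values per spot of Nr4a2, at close to 1 UMI, and leaves Ntng2 and Npsr1, with 10 and 16 and with 1 and 2 UMIs, too shallow to compare.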

Other observations

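All tests below were chosen after the result they address was seen, except that of the mix of regions on the cell cycle list. Some gene groups differed between regions in ways not described above. The ependyma list holds 5 genes, of which 3 were measured over the whole sections, with a median near 0. Too few of them were measured in most pairs, and only 4 pairs had a median, from -0.19 to 1.99. It was 1.99 in the germinal pair and 1.95 in the Gng8 and Pou4f1 pair. In meninges the interferon and MHC class I list had a median of 0.72 and the vessel list 0.43, and in the Gng8 and Pou4f1 pair the interferon list had a median of 0.71. Microglial genes had medians of 0.71 in the latter pair and -1.28 in the Fezf2 and Npy pair, whose P0 cluster is unnamed. The claustrum list had its highest median over the 12 pairs, 0.92, in that pair.

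Immediate early genes differed in direction between regions, with medians of 0.90 in the germinal pair, 0.73 in choroid plexus and 0.72 in meninges, and of -0.38 in the Fezf2 and Npy pair and -0.25 in the matched thalamus clusters. The glucocorticoid and thyroid hormone list had medians of 0.79 in choroid plexus and -0.30 in hypothalamus. In the hypothalamus the oligodendrocyte precursor and astrocyte lists had medians of 0.68 and 0.53. These differences between regions were not tested.

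Transcripts of hypothalamus and choroid plexus were found in every cluster of a section, and RNA carried over the tissue or between barcodes is a candidate explanation. Pmch in the lowest E17 cluster outside hypothalamus was at 0.778 of the median of those 13 clusters, 83.4 CPM, and its dispersion among upper layer spots was 0.816, as close to Poisson as an even background would give. Avp at P0 in its lowest such cluster was at 0.611 of a median of 120 CPM over 16 clusters with a dispersion of 0.995, although meninges held 1565 CPM. In E17 upper layers, 6 other choroid plexus genes stood to Ttr in 1.17 times their ratio in choroid plexus (0.971 to 1.39, 137 UMIs), as 1 shared source would give. These values are consistent with carry-over and leave low local expression of Pmch or Avp open, and no biological explanation was tested.

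Cell cycle and progenitor genes were lower in the P0 section, where a different mix of regions may contribute. With the same mix of joint clusters the cell cycle median was -0.59 (-0.70 to -0.49), against -1.0004 without it, which met neither the median above -0.2 set beforehand for the mix as the cause nor, by its upper bound alone, the interval wholly below -0.5 set against it. The interval was drawn from summed counts without the weights of the mix, so it may be too narrow, and a bound this near -0.5 decides little. Regions could still differ inside a joint cluster. The one led by Eomes and Dlx6os1 at E17 was led by Igfbpl1 and Fam210b at P0, and another held 16 unnamed spots at E17 and 160 striatum spots at P0. Fewer ventricular zone cells of every kind in the germinal pair were weighed next: there radial glia genes lay 1.02 above the cell cycle genes on the log2 scale (0.61 to 1.46), with medians of 0.38 and -0.64, the latter also without the 2 members among the leading genes of the pair. Astrocytes express several of the radial glia genes and their list was at 1.06, so fewer ventricular zone cells and more astrocytes cannot be told apart from a shift within the lineage. The stage itself stays open and untested, as it is confounded with the section and the animal.

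A difference in sex between the animals is a candidate explanation for the sex-linked genes. The 4 Y-linked genes of the list had 1 UMI at E17 and 4342 at P0. Of the 7 genes annotated on chromosome Y that had UMIs, Gm47283 alone had over 10 in both sections, 9400 and 20925, and it lies at the distal, pseudoautosomal end of that chromosome, a part shared with X. The genes Kdm5c, Eif2s3x, Ddx3x and Pbdc1, which escape X inactivation, were 1.45-fold, 1.61-fold, 1.31-fold and 1.43-fold higher at E17, and their median lay at -0.46 relative to autosomal genes, in the direction of 2 active copies at E17. These values are consistent with a female E17 and a male P0 animal, so sex is confounded with stage in every comparison above.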
